A study of Drosophila melanogaster with 2 samples.

How the data were processed

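The series holds 1 group of 2 samples: chromatin immunoprecipitation with sequencing (ChIP-seq) on whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, from a transgenic line that carries disco-r fused to the fluorescent tag eGFP, precipitated with an antibody against GFP. Per the labels, chromatin was sheared by sonication to 200 to 800 bp, and the samples are biological replicates 2 and 3. One label names disco, the neighbouring paralog, as the fused gene where the other labels name disco-r, so both loci are described. No input or control library was analysed here.

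Values were taken as deposited. For each replicate the authors deposited a list of candidate regions, peaks and background together, derived per the file headers and accompanying notes from that replicate's alignments and 1 control file. A pooled candidate list was derived, per the deposited notes, from both replicates' alignments and the same control. The list thresholded by irreproducible discovery rate (IDR, a measure of how alike the replicates rank regions) came from the pooled list and both replicates' lists, per the same notes. The aligner, the peak caller, the IDR threshold and the number of reads are not given in the sources used here, so the sequencing depth is unknown. Each region carries the peak caller's signal value as deposited by the authors, a positive number with no stated scale, used here only to rank, filter or describe regions within 1 list. The deposited −log10 q-value was checked and not used in any test, because in the dm6 IDR list it is 3.68 in every row. Summits were read from the deposited offset of the summit from the region's start.

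The dm6 lists hold 29347 pooled candidates, 2334 IDR peaks and 30000 candidates per replicate. Most pooled regions are 400 bp wide, and 280 are not (100 to 451 bp). One interval, on X from 16105013 to 16105377, stands in the list 2 times with different summits and was kept as deposited. Fixed region widths and the fixed number of candidates per replicate follow from the authors' processing, so neither a width nor the length of a candidate list measures binding.

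Genes, transcripts and coding regions came from Ensembl release 115 (annotation BDGP6.54), and sequence from the Release 6 assembly of the fly genome, which is dm6. Of the fixed gene symbols, 4 were matched under a newer name in the annotation. For dm3 no genome was used here, so those lists were only counted, per chromosome arm too, and compared between replicates, and no coordinate was converted between builds. Each summit was put in 1 class, in this order: promoter (within 500 bp of a protein-coding transcription start site, TSS), 5′ UTR, 3′ UTR, coding exon, intron, other transcribed (non-coding genes) and intergenic. A gene was said to have a peak where a summit lay in its body or within 2 kb on either side, which does not make it a target, and neighbouring genes can share 1 summit.

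The tests, the 21 gene lists, the 24 motif consensus sequences and the rule for named genes were fixed before the data were examined. The rule names disco-r and disco, the gene at each of the 20 strongest peaks found in both replicates, the 10 genes with the most peaks, and from each list up to 4 members with the strongest peaks; 1 item that the rule names is not reported here. Shares per class and per arm were compared between IDR peaks and the 26517 pooled candidates that neither passed IDR nor overlapped a peak, with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment. Intervals of shares are 95% Wilson intervals and cover counting error only. Signal at promoters was compared with signal elsewhere by a two-sided permutation test on medians with 100000 resamples. Gene lists were compared with all protein-coding genes that had a candidate, within 10 strata of locus length, by an exact two-sided test of the stratified hypergeometric distribution. Motifs and all 2080 6-mers were counted within 100 bp of the summit, on either strand, against 10737 candidates sampled to the GC content of the peaks in bins of 5%. Peaks and genes are not independent replicates, so p-values compare positions in these lists and not embryos, and no p-value is given for correlations across peaks. The comparison of disco-r with the rest of the genome used windows of the same size at steps of 10 kb.

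Alternatives were a stricter list of the IDR peaks above their median signal, each replicate's strongest 2334 candidates alone, the dm3 lists for counts and replicate agreement, an overlap of 1 bp, arms 2L, 2R, 3L, 3R and X only, promoters of 200 or 1000 bp, random placements of summits, arm length, the gene with the nearest TSS, strata by the number of candidates per gene, a motif distance of 50 bp, and flanks of the same peaks 500 bp away. Matching on promoter as well as GC content, promoter summits only, peaks drawn at random from the candidates, 50 bp for 6-mers, and arms without the 50 kb around disco-r were added after the data had been seen. The flanks were not matched on GC content. Gene lists by the nearest TSS also used strata by the number of candidates per gene.

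The procedures were tested on simulated peaks drawn from the real candidates. Where promoters were drawn with a weight of 3, they were called in 100 of 100 draws with a median odds ratio of 3.17, and where ribosomal protein genes had that weight their list was called in 100 of 100 draws. With the weight on promoters alone the gene list test was misled: it called ribosomal protein genes in 20 of 100 draws and at least 1 other list in 34. With nothing planted these counts were already 12 and 13 of 100. A word implanted in 10% of peaks ranked first among 6-mers in 10 of 10 draws, with up to 9 other words called beside it, and 0 words were called without it. With nothing planted, promoters were called in 8 of 100 draws, and the permutation test gave p under 0.05 in 15 of 200 draws. The gene list test with length strata was biased by the number of candidates per gene: with nothing planted it called at least 1 list in 30 of 200 draws (15.0%), and its mean ratio of observed to expected was 1.33 for ribosomal protein genes, 0.667 for chemoreceptor genes and 1.42 for hormone response genes. With strata by candidates per gene at least 1 list was called in 9 of 200 draws (4.5%), and these means were 0.998, 0.989 and 1.24. The fixed test was kept, and values from candidate strata and from peaks drawn at random stand beside it for the 2 lists it called; the other lists' ratios are from the fixed test unless stated. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.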

Results

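Genome-wide occupancy of the tagged zinc-finger protein disco-r, which together with its paralog disco patterns the embryonic head and the leg primordia, was profiled in whole fly embryos collected over the first 24 h of development. An eGFP tag on disco-r was precipitated from mixed-sex embryos with an antibody against GFP in 2 biological replicates, numbered 2 and 3. There was 1 group and no contrast between conditions, so the data address where the tagged protein was enriched and how far the replicates matched. Each replicate contributed 30000 candidate regions, the pooled list held 29347, and 2334 passed IDR (dm6). The number of reads behind these lists is unknown. The signal of a peak is the authors' own value and is given here only within a list.

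Most of the strongest candidates were shared by the replicates. Of the strongest 2334 candidates of replicate 2, 66.7% (95% Wilson interval 64.8 to 68.6) overlapped one of the strongest 2334 of replicate 3, against a mean of 7.26% for candidates of replicate 3 drawn at random. From replicate 3 to replicate 2 the share was 67.2% (65.2 to 69.1), against 7.48% at random. The replicates' lists were derived with the same control, which the random draws do not take into account, so any likeness due to it was not separated. The IDR list was built from these replicates, so its overlap with their 30000 candidates each is no separate measure: 2329 of 2334 peaks (99.8%, 99.5 to 99.9) were overlapped by at least 50% of their length in replicate 2, and 2324 (99.6%, 99.2 to 99.8) in replicate 3. Across 2319 peaks found in both, signal in the replicates had a Spearman's rho of 0.607 and, on the log2 scale, a Pearson's r of 0.72. The log2 ratio of replicate 3 to replicate 2 had a median of -0.05 and an SD of 0.55. The IDR list equalled the 2334 strongest pooled candidates, so it was in effect a threshold on pooled signal at 72.5. The correlations above therefore describe only peaks selected on signal pooled from the same replicates. In dm3, 2251 of 21845 pooled candidates passed, and the X chromosome held 18.5% of peaks in both builds.

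Peaks of tagged disco-r lay at promoters more often than other candidates did. Of the 2334 IDR peaks, 1215 (52.1%, 50.03 to 54.1) had their summit within 500 bp of a protein-coding TSS, against 24.4% (23.9 to 24.9) of 26517 candidates that did not pass (odds ratio 3.36, 95% interval 3.08 to 3.66, adjusted p = 9.5e-163, Fisher's exact test). Coding exons were nearly free of peaks, with 5 summits (0.214%) against 13.2% of candidates (odds ratio 0.0141, 0.00457 to 0.033, adjusted exact p = 8.7e-127). These 5, named here because they are few, lay in the homeobox gene otp (2R, 20884476 to 20884718, signal 422), the phosphodiesterase gene Pde1c (2L, 11816488 to 11816690, signal 277), l(3)mbn (3L, 6124767 to 6124882, signal 128), CG10357 (3L, 3616342 to 3616741, signal 83.6) and klar (3L, 505975 to 506374, signal 83.5). Introns held 767 peaks (32.9% against 37.7%, odds ratio 0.81, adjusted exact p = 5.3e-06), intergenic sequence 262 (11.2% against 18.4%, odds ratio 0.56, adjusted exact p = 1.4e-19) and 3′ UTRs 18 (0.771% against 3.02%, odds ratio 0.249, adjusted exact p = 7.4e-13). In 5′ UTRs (0.771% against 1.04%, adjusted exact p = 0.327) and non-coding genes (2.1% against 2.21%, adjusted exact p = 0.825) the shares did not differ detectably. With promoters of 200 bp introns no longer passed (odds ratio 0.966, adjusted exact p = 0.515), and with promoters of 1000 bp 5′ UTRs did (odds ratio 0.244, adjusted exact p = 0.00572). Against random placements on the same arm 3′ UTRs stood at 0.143 and intergenic sequence at 0.329.

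The promoter share held in each replicate. It was 52.7% (odds ratio 3.25) among the strongest 2334 candidates of replicate 2 and 52.3% (odds ratio 4.36) among those of replicate 3. Against summits placed at random on the same arm the odds ratio was 8.4. The strongest 233 peaks included 148 at promoters (63.5%, 57.2 to 69.4), and ranks 1168 to 2334 included 566 (48.5%, 45.6 to 51.4). Promoter peaks had a median signal of 108 against 100.5 for the others (difference 7.77, permutation p = 8.6e-04). In the replicates' own signal values, whose sizes cannot be set against the pooled ones, the difference was 2.74 in replicate 2 (permutation p = 0.00789) and 2.08 in replicate 3 (permutation p = 0.05002, just above the threshold). With promoters of 200 bp the pooled difference was 2.81 and no longer passed (permutation p = 0.316).

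**Figure D1:**
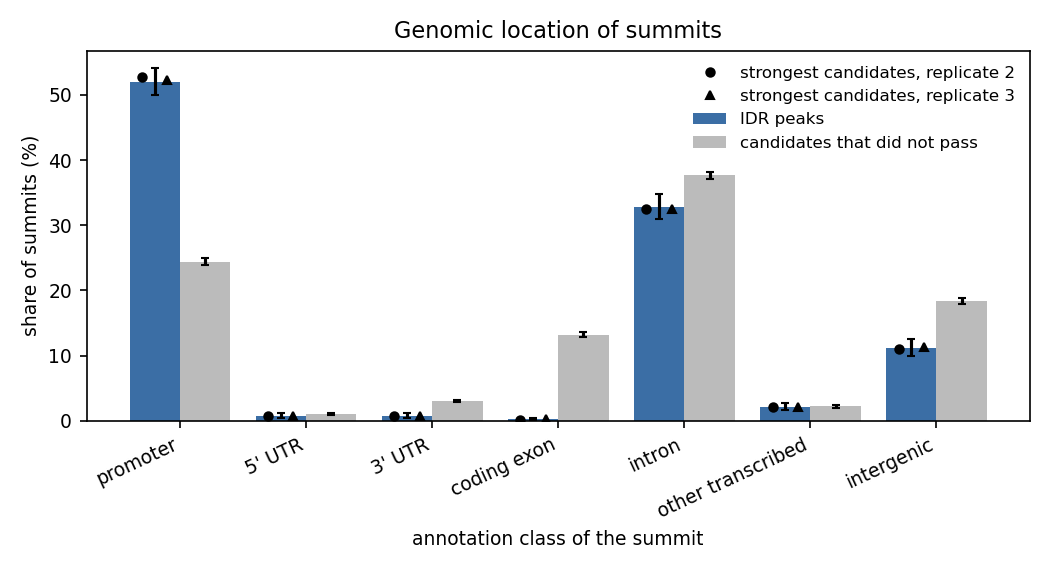
Share of summits (%) in each annotation class for the 2334 IDR peaks (blue bars) and 26517 candidates that did not pass (grey bars), with 95% Wilson intervals; black symbols give the strongest 2334 candidates of replicate 2 (circles) and replicate 3 (triangles). Promoters held 52.1% of IDR peaks against 24.4% of the other candidates, and coding exons 0.214% against 13.2%.

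The strongest peaks lay mostly at promoters and in introns, at genes of varied function. The strongest of all (signal 1206, 3L, 19590445 to 19590785) lay 99 bp from the TSS of CG14100, between it and ash1, a Trithorax-group histone methyltransferase gene. The second (signal 1187, 2L, 480905 to 481267) lay in an intron of ush, which encodes a GATA-factor cofactor active in blood cells and the dorsal ectoderm. Promoter peaks followed at px, a wing vein gene (signal 888), Ugalt, a UDP-galactose transporter gene (884), Chro, a chromodomain protein gene (769.8), the arginine methyltransferase gene Art3 (768), the mitochondrial ribosomal gene mRpL41 (765), the Polycomb gene ph-p (742, X, 2137190 to 2137529), PNPase (728), CenG1A (725) and the casein kinase gene gish (598). Intron peaks lay in CG11050 (823), the kinase gene Lk6 (793), CG32772 (637), CG9663 (606) and osa, which encodes a chromatin remodelling subunit (591). Promoter peaks of CG1888 (761) and CG31145 (644), a non-coding gene near CG4004 (758) and an intergenic site 11908 bp from the TSS of CG13323 (744) complete the 20. Of these 20 peaks 12 were at promoters, and all ranked within the first 21 in replicate 2 and the first 24 in replicate 3.

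A few genes held several peaks each. They were ranked by count and not by density, and their lengths ran from 27.0 kb (CHES-1-like) to 394 kb (kirre). Raf, the MAP kinase kinase kinase of receptor tyrosine kinase signalling, and CG1677 each had 10 peaks, and the ecdysone-response receptor gene Hr4 had 9. The gene ush had 8, as did the forkhead gene CHES-1-like and kirre, a gene on the fixed list of mesoderm and muscle regulators. The Cullin adaptor gene rdx had 7, and tara, sick and the ecdysone-induced receptor gene Eip75B had 6 each. Among the strongest candidates of replicate 2 alone kirre had 5 and sick 3, and among those of replicate 3 alone 10 and 6. Of these 10 genes 5 lie on X. In all, 3096 of the 11296 protein-coding genes with a candidate (27.4%) had an IDR peak, 2477 of them exactly 1 and 64 at least 4. The strongest candidates of replicate 2 gave 2976 genes and those of replicate 3 3098, with 2358 in common. By the nearest TSS instead, 1801 genes had a peak.

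The X chromosome held more of the IDR peaks than of the other candidates, and 3L fewer. X had 431 peaks (18.5%, 16.9 to 20.1) against 14.3% of candidates (odds ratio 1.35, 1.21 to 1.51, adjusted exact p = 8.8e-07), with odds ratios of 1.17 in replicate 2 and 1.41 in replicate 3. On 3L there were 440 (18.9% against 22.0%, odds ratio 0.822, adjusted exact p = 0.00101), and among the stronger 1167 peaks 3L no longer passed (odds ratio 0.85, adjusted exact p = 0.0657). Chromosomes 2L, 2R, 3R and 4 did not pass (adjusted exact p = 0.702, 0.527, 0.16 and 0.178). Among the stronger peaks 3R had fewer (odds ratio 0.824, adjusted exact p = 0.0229), and chromosome 4 had fewer in replicate 2 alone (0.44, adjusted exact p = 0.0195) and against arm length (0.423, adjusted exact binomial p = 0.0152), where 2L had more (1.14, adjusted exact binomial p = 0.0228). The excess on X depends on the background: against arm length, 18.5% of peaks stood beside 17.6% of sequence (exact binomial test, adjusted p = 0.397).

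Ribosomal protein genes stood out among the 21 fixed lists. Of 85 with a candidate, 62 (72.9%, 62.7 to 81.2) had an IDR peak, where 22.5% were expected from locus length (ratio 3.24, adjusted exact p = 4.9e-22), with ratios of 3.45 in replicate 2 and 3.39 in replicate 3. With strata by candidates per gene, which on simulated peaks with no effect planted brought the list's mean ratio from 1.33 to 0.998, the ratio was 2.64 (adjusted exact p = 4.7e-18), and with peaks drawn at random from the candidates it was 3.39 (adjusted permutation p = 0.0042, from the smallest p the draws can give). By the gene with the nearest TSS, with candidate strata, it was 5.22 (adjusted exact p = 1.4e-30). Strong peaks lay at RpS27 (signal 447, 3 bp from its TSS), RpL7 (386, 31 bp) and RpL34b (292, 74 bp). At 59 of 82 ribosomal protein genes with a promoter candidate (72.0%) the summit lay within 500 bp of their own TSS, against 22.2% of 6942 other genes. Transfer RNA genes, which RNA polymerase III transcribes at high rates, also had a summit within 500 bp more often than random windows did, 13 of 290 genes against 5.33 expected (ratio 2.44, 95% interval 1.21 to 4.03); the 13 lay in 11 of 174 clusters and had 11 distinct summits.

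Chemoreceptor genes, used as a group little expressed in embryos, had few peaks: 6 of 91 (6.59%, 3.06 to 13.6) against 24.6% expected from length (ratio 0.268, adjusted exact p = 1.1e-04). This did not hold once the number of candidates was taken into account over the same genes. With candidate strata 15.2% were expected (ratio 0.433, adjusted exact p = 0.162), and draws from the candidates gave 12.0% (ratio 0.551, adjusted permutation p = 0.692). By the gene with the nearest TSS, with candidate strata, it passed (ratio 0.165, adjusted exact p = 0.00316). The summit at Or85f was that of RpL34b, and Ir68b (signal 282), Gr94a (165) and Ir31a (98.2) had summits over 2000 bp from their TSS.

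No list of developmental regulators passed the test in either direction, nor did any with candidate strata (adjusted exact p from 0.208 to 1) or peaks drawn from the candidates (adjusted permutation p from 0.563 to 1). Among chromatin regulators of the Polycomb and Trithorax groups 7 of 12 had a peak (ratio 1.72, adjusted exact p = 0.568), among them ph-p with 3, Trl, the GAGA factor gene, with 5 (highest signal 471), and Pc (371), besides the peak between CG14100 and ash1. Hormone response genes had peaks at 8 of 12 (ratio 1.56, adjusted exact p = 0.568), with Hr4 (246), Hr3 (237), Eip75B (179.9) and EcR (179) the highest; with peaks drawn from the candidates the ratio was 0.924. Notch pathway genes had peaks at 8 of 16 (ratio 1.59, adjusted exact p = 0.568), with E(spl)m8-HLH (349), N (159.8), neur (155) and E(spl)m3-HLH (139). In the Wnt pathway 7 of 14 had one (ratio 1.26, adjusted exact p = 0.689), with fz (219), Wnt5 (155), Wnt6 (100.4) and arr (93.2); with candidate strata the ratio was 0.971, by draws 0.916 and with replicate 3 alone 0.687 (4 of 15).

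Lists of patterning genes did not pass either. Of 20 appendage patterning genes 7 had a peak (ratio 0.901, adjusted exact p = 0.956): bowl (201), disco-r (139), disco (134) and dac (100.4) had the strongest. Only Antp (93.7) of 8 Hox genes had one (ratio 0.296, adjusted exact p = 0.568), and with replicate 3 alone 2 had one (ratio 0.602, adjusted exact p = 0.776). Gap and head gap genes had 3 of 12, at cad (129.9), oc (98.8) and cnc (98.0), and pair-rule and segment polarity genes 3 of 16, at H15 (91.3), ptc (88.7) and en (77.0), with adjusted exact p = 0.956 and 0.587. With replicate 3 alone the ratio of pair-rule and segment polarity genes moved from 0.58 to 0.378 (2 of 17).

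Lists of markers of single tissues did not pass, and adjusted p ran from 0.568 to 1 over the 19 lists of regulators, pathways and tissues. Mesoderm and muscle regulators had 7 of 16, led by Mef2, the muscle differentiation factor gene, with 4 peaks and a highest signal of 562, then kirre (188), zfh1 (164) and how (129); muscle structural genes had 3 of 13, sls (156), Tm1 (104) and Zasp52 (95.4). Glial genes had 5 of 10, at moody (254), Gs2 (190.2), pnt (159), nrv2 (98.4) and loco (81.2), and neuronal genes 3 of 16, at the pan-neuronal gene elav (204), grh (154) and pros (96.6). Amnioserosa and dorsal ectoderm genes had 6 of 12, with ush, Ance (276), tup (152) and dpp (130.3) highest. Gut genes had 4 of 11, at bowl, fkh (192), cad and Hnf4 (95.7). Hemocyte genes had 2 of 12 (ush and vkg, 111), tracheal genes 2 of 12 (rib, 156, and bnl, 106), epidermal genes 4 of 13 (grh, ovo, 85.5, Egfr, 81.6, and mwh, 76.7), germline genes 2 of 9 (bgcn, 185, and vas, 74.98) and circadian genes 2 of 8 (Pdp1, 154, and vri, 81.1). With replicate 2 alone, mesoderm and muscle regulators had 4 of 16 (ratio 0.694 against 1.18), epidermal genes 2 of 12 (0.444 against 0.818), tracheal genes 3 of 12 (0.742 against 0.487) and germline genes 3 of 9 (1.19 against 0.765), and with replicate 3 alone hemocyte genes had 1 of 11 (0.266 against 0.487); none passed. Lists of 8 to 20 genes leave wide intervals, and a gene in 2 lists was counted in both.

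**Figure D2:**
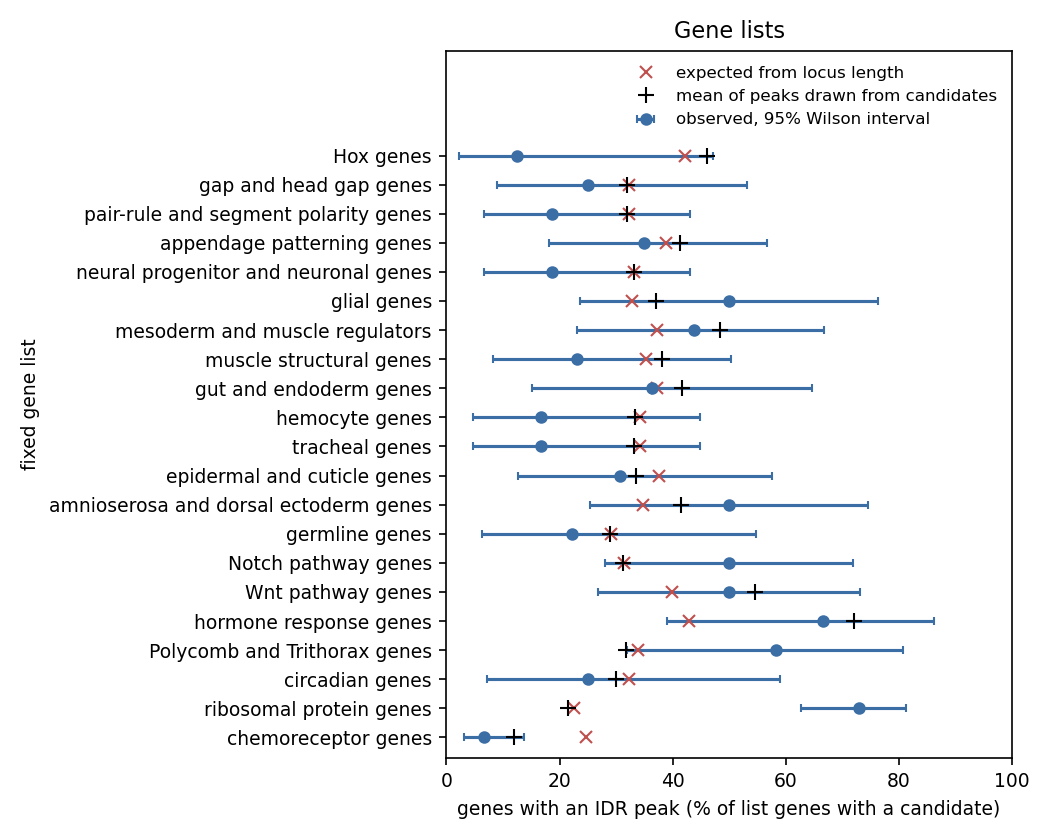
Share of each fixed list's genes with an IDR peak (%, blue points with 95% Wilson intervals), the share expected from locus length (red crosses) and the mean share with peaks drawn at random from the candidates (black plus signs). Ribosomal protein genes stood at 72.9% against 22.5% expected from length, and chemoreceptor genes at 6.59% against 24.6% from length but 12.0% from the draws.

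The 50 kb on either side of disco-r were rich in peaks, the strongest of them nearer to other genes. Within 50 kb of the gene (X, 16118067 to 16148977, minus strand) lay 12 IDR peaks in 11 distinct intervals, more than in 99.7% of windows of that size, whose median was 2. The strongest candidates gave 12 in replicate 2 (99.5th percentile) and 10 in replicate 3 (98.8th percentile). The strongest site (signal 361, summit 16105143) was at the promoter of CG42353 and the second (293, 16090309 to 16090496) in an intron of Tob. They lay 19189 and 33962 bp from the nearest TSS of disco-r. At the disco-r promoter a peak (signal 139, 16148942 to 16149341) had its summit 165 bp from the TSS, with others 1773 bp (134) and 9706 bp (156) upstream. Inside the gene lay 2 more, in an intron (16140652 to 16141051, signal 91.0) and at an internal TSS (16123847 to 16124246, signal 76.4). The paralog disco (X, 16210598 to 16216750, minus strand) had 1 peak within 50 kb, 391 bp from its TSS (16216941 to 16217340, signal 134), and 2 among the strongest candidates of replicate 3 alone (52.9th percentile). Pooled candidates were also many near disco-r, 54 against a median of 30 per window (94.3rd percentile), and 13 near disco (24.2nd percentile).

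**Figure D3:**
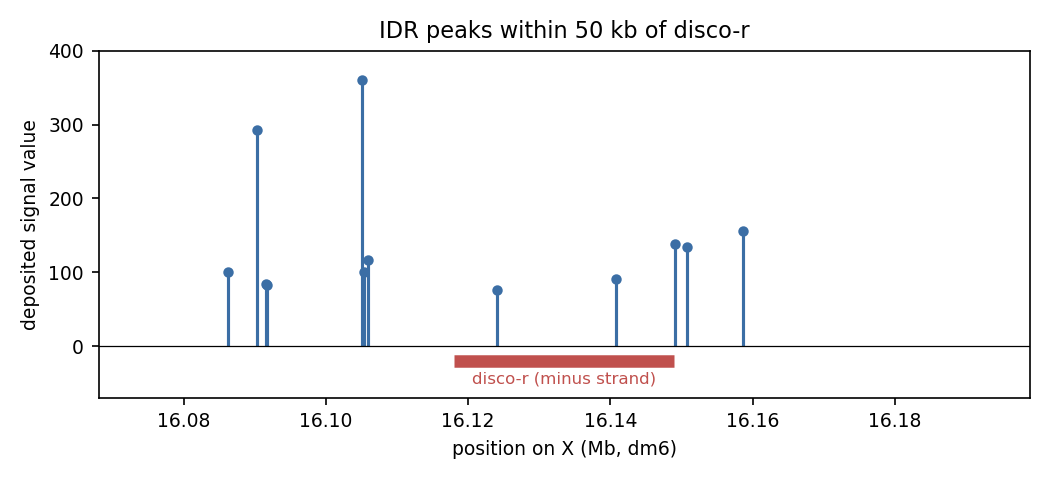
Position on X (Mb, dm6) and deposited signal value of the 12 IDR peaks within 50 kb of disco-r, drawn as stems at their summits, with the gene as a red bar. The highest stems, 361 and 293, stand downstream of the gene, and the stem of 139 stands at its promoter.

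Of 24 fixed consensus sequences, 4 were more frequent and 3 less frequent in peaks than in candidates of the same GC content. The core of the insulator protein CTCF was in 2.74% of peaks against 0.969% (odds ratio 2.88, 2.07 to 3.99, adjusted exact p = 9.6e-09), the GAGA factor word in 4.84% against 3.0% (1.65, adjusted exact p = 2.2e-04), the word shared by DREF and BEAF-32 in 3.77% against 2.34% (1.64, adjusted exact p = 0.00104) and the E-box CAGCTG in 10.2% against 7.59% (1.38, adjusted exact p = 3.6e-04). The Exd-Hox word (odds ratio 0.801, adjusted exact p = 0.0043), the homeodomain word (0.839, adjusted exact p = 0.0306) and the Sp/KLF word (0.417, adjusted exact p = 0.00249) were less frequent, all adjusted over the list alone. With candidates matched on promoter as well, only CTCF (2.94, adjusted exact p = 1.1e-07) and GAGA factor (1.49, adjusted exact p = 0.0129) still passed. The word of DREF and BEAF-32 (0.932, adjusted exact p = 0.916), the E-box CAGCTG (1.21, adjusted exact p = 0.0954), Exd-Hox (0.835, adjusted exact p = 0.0783), the homeodomain word (0.868, adjusted exact p = 0.191) and Sp/KLF (0.492, adjusted exact p = 0.0783) did not.

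Other alternatives also ended calls. One of them, the flanks of the same peaks, was not matched on GC content, so it does not separate words from base composition. Among the stronger 1167 peaks DREF and BEAF-32 (1.55, adjusted exact p = 0.0664), the E-box CAGCTG (1.24, adjusted exact p = 0.237), the homeodomain word (0.847, adjusted exact p = 0.241) and Sp/KLF (0.434, adjusted exact p = 0.116) did not pass. Within 50 bp CTCF rose to 4.66 (adjusted exact p = 8.4e-10), while GAGA factor (1.45, adjusted exact p = 0.147), the homeodomain word (0.80, adjusted exact p = 0.0675) and Sp/KLF (0.494, adjusted exact p = 0.165) did not pass, and on the 5 large arms the homeodomain word did not (0.852, adjusted exact p = 0.0602). Against the flanks of the same peaks DREF and BEAF-32 stood at 6.27 (adjusted exact p = 2.9e-19), CTCF at 4.08 (adjusted exact p = 1.0e-10) and Sp/KLF at 0.182 (adjusted exact p = 6.1e-14), all still past the threshold, while the homeodomain word was more frequent (1.2, adjusted exact p = 0.043), Exd-Hox stood at 1.13 (adjusted exact p = 0.227), GAGA factor at 0.845 (adjusted exact p = 0.257) and the E-box CAGCTG at 1.05 (adjusted exact p = 0.681).

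The remaining 17 consensus sequences did not pass, and 10 of them passed in no alternative. The M1BP word (odds ratio 1.36, adjusted exact p = 0.301) passed in the strongest candidates of replicate 3 alone (2.02, adjusted exact p = 0.00235) and of replicate 2 alone (1.65, adjusted exact p = 0.0288) and against the flanks (2.52, adjusted exact p = 0.00114), and stood at 0.807 with promoter matching. The Snail E-box (1.07, adjusted exact p = 0.744) passed among the stronger peaks (1.45, adjusted exact p = 0.0274) and was less frequent than in the flanks (0.739, adjusted exact p = 0.00598). Against flanks alone, Hth/Meis (1.27), Mef2 (1.65), Forkhead (1.47) and TATA (1.63) were more and CA repeats less frequent (0.558). The flanks were not matched on GC content, so base composition was not separated from these calls.

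Of 2080 6-mers 136 were more and 147 less frequent in peaks. The word ACAGTG led, in 20.5% of peaks against 11.1% of matched candidates (odds ratio 2.05, adjusted exact p = 9.6e-28), with 2.15 and 2.07 from the strongest candidates of replicate 3 and replicate 2 alone. Next came ACACTG (19.6% against 12.1%, odds ratio 1.77), CTGTGC (1.68) and ACTGTG (1.69), with adjusted p of 3.0e-17, 2.0e-11 and 3.3e-11. The word CGATAG (1.67, adjusted exact p = 3.7e-08) no longer passed with promoter matching (1.11, adjusted exact p = 0.454) or among the stronger 1167 peaks (1.37, adjusted exact p = 0.0915). Against the flanks, which were not matched on GC content, ACACTG stood at 2.95 and CGATAG at 2.62. Copies of ACAGTG were densest 80 to 120 bp on either side of the summit, at 1.61 per kb, and thinner within 40 bp of it (0.782 and 0.964 per kb).

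**Figure D4:**
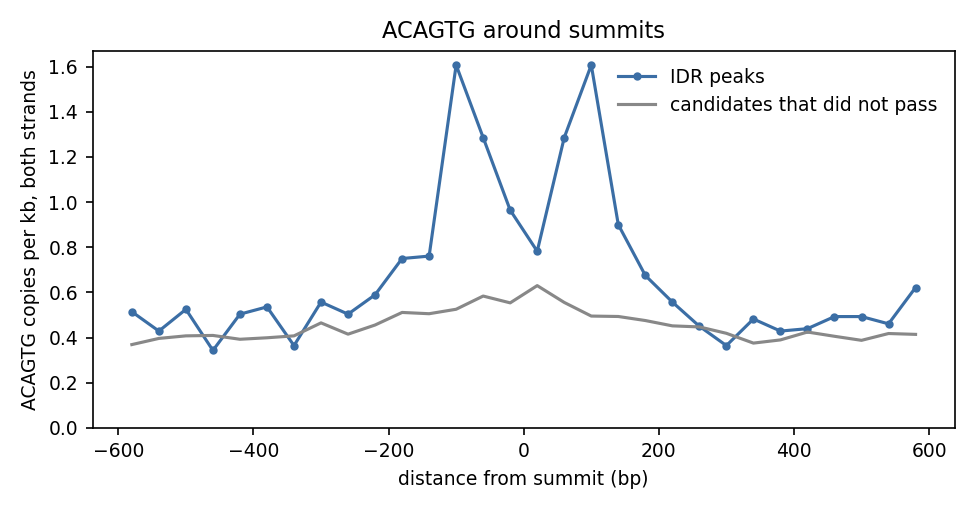
Copies of ACAGTG per kb on both strands against distance from the summit (bp, bins of 40 bp) for the 2334 IDR peaks (blue) and the candidates that did not pass, not matched on GC content (grey). Density in peaks reaches 1.61 per kb at 80 to 120 bp on both sides and dips at the summit.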

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

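Promoter matching, promoter summits only, peaks drawn at random, 50 bp for 6-mers, leaving out the surroundings of disco-r, and all alternatives for the disco-r locus were chosen after the results had been seen; the others were planned. The promoter excess kept its direction and its side of the threshold in all 7 alternatives (odds ratio 2.99 to 8.4), the ribosomal protein list in all 8 (ratio 2.64 to 5.22) and ACAGTG in all 6 (odds ratio 1.72 to 2.7). Where a change below does not follow from how the alternative is built (fewer peaks, another background), the cause was not tested. With an overlap of 1 bp, 99.9% of peaks were found in both replicates and 69.7% of the strongest candidates were shared; among the stronger 1167 peaks 72.1% were shared, 1762 genes had a peak, 4 motifs and 98 6-mers passed, and 6 peaks remained near disco-r. By the nearest TSS, 1801 genes had a peak. The pooled signal difference, 7.77, was 2.81 with promoters of 200 bp; with a replicate left out it was 2.08 or 2.74 in the other's own signal values, which are not on the pooled scale, so only their direction and test compare. Against arm length the odds ratio of X was 1.06. The number of motifs past the threshold, 7, became 4 within 50 bp, 11 against flanks and 2 with promoter matching. That of 6-mers, 283, became 93, 1216 and 144. The flanks were not matched on GC content. Of the 2 gene lists called, 1 remained with strata by candidates per gene, 1 with random draws and 1 with promoter summits only: chemoreceptor genes were lost, at 0.433, 0.551 and 0. Lists that did not pass changed sides of 1 as follows. In the stronger peaks, gut genes stood at 1.24 and Wnt genes at 0.602. By the nearest TSS together with candidate strata, appendage genes stood at 1.16, mesoderm regulators at 0.902, germline genes at 1.45, Wnt genes at 0.859 and circadian genes at 1.1. With candidate strata, mesoderm regulators stood at 0.922 and Wnt genes at 0.971, and with random draws mesoderm regulators at 0.905, Wnt genes at 0.916 and hormone response genes at 0.924. With promoter summits only, values were 1.31 (gap), 0.713 (glial), 0.315 (mesoderm), 1.49 (gut), 0.422 (amnioserosa), 1.02 (germline), 0.376 (Wnt), 0.736 (hormone) and 1.03 (circadian). With either replicate left out, ratios ran from 0.774 to 1.09 (appendage), 0.694 to 0.977 (mesoderm), 0.988 to 1.25 (gut), 0.687 to 1.35 (Wnt) and 0.768 to 1.19 (germline), and odds ratios from 0.9998 to 1.04 (2L), 0.997 to 1.05 (2R), 0.917 to 1.01 (other transcribed), 0.958 to 1.1 (Forkhead) and 0.891 to 1.14 (CA repeat). In the stronger peaks 2R stood at 0.993, M1BP at 0.902 and TATA at 1.04. On the 5 large arms the CA repeat stood at 1.02, and against random placements other transcribed sequence at 1.06. Within 50 bp Mef2 stood at 0.943 and TATA at 1.02. Against the flanks GAGA factor stood at 0.845, the homeodomain word at 1.2, Exd-Hox at 1.13, Snail at 0.739, Forkhead at 1.47 and TATA at 1.63, and with promoter matching DREF and BEAF-32 at 0.932 and M1BP at 0.807. Read depth is unknown, so nothing here shows what deeper sequencing would change. No paired analysis was possible because there is 1 group.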

Other observations

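The tests of extra copies and of 1 replicate at disco-r, and of the added gene groups, summit sides, X by location, the matching on promoter for ACAGTG and its rise at other candidates were chosen after the result had been seen; the others were set down first. Of 10 further gene groups written down and tested after the fixed lists had been read, 1 passed: 25 of 71 mitochondrial ribosomal protein genes had an IDR peak (35.2%), where peaks drawn at random from the candidates gave 18.9% (ratio 1.86, adjusted permutation p = 0.018). It passed with replicate 3 alone (ratio 1.97, adjusted permutation p = 0.012) and not with replicate 2 alone (ratio 1.45, adjusted permutation p = 0.214). The strongest peaks lay at mRpS10 (signal 768, shared with Art3), mRpL41 (765), mRpS23 (725, shared with CenG1A) and mRpL23 (348). The draws did not take promoters into account, and no test with promoter summits only was run for this group. Promoters held 52.1% of all IDR peaks against 24.4% of the other candidates, so the ratio of 1.86 was not separated from the promoter excess. Cytochrome P450 genes, mostly detoxification enzymes, had peaks at 3 of 66 (Cyp9f2, Cyp6u1 and Cyp6v1; 14.7% by draws, adjusted permutation p = 0.159), and cuticular protein genes at 3 of 73 (Cpr76Ba, Cpr31A and Cpr73D; 12.7% by draws, adjusted permutation p = 0.222). Neither passed, nor did the remaining groups: translation initiation factors (14 of 41), ATP synthase and respiratory chain subunits (17 of 63), proteasome subunits (9 of 39), cyclin, Cdk and checkpoint genes (8 of 21), odorant-binding proteins (5 of 31), COP9, exosome and splicing Sm/Lsm genes (3 of 22) and Jonah and trypsin proteases (0 of 13), with adjusted permutation p from 0.247 to 0.827. Groups were drawn by gene name, so 1 may hold genes of another kind: of the 3 in the COP9, exosome and splicing group, Rrp46 and Rrp40 are exosome genes and Rrp1 is a DNA repair gene.

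Promoter peaks had a side. Their summits lay a median of 92 bp upstream of the nearest TSS (-92 bp in the direction of transcription), and 79.3% (76.9 to 81.4) were upstream, against a median of -10 bp and 52.2% (51.0 to 53.4) for promoter candidates that did not pass. A summit between 2 divergent TSSs is upstream of both. Divergent pairs held 35.1% of promoter peaks and 16.6% of the other promoter candidates, so part of the difference may be built in. It was not computed without such pairs. On X the excess of peaks over candidates lay outside promoters: 237 of 1119 such peaks (21.2%) were on X against 13.9% of candidates (odds ratio 1.67, 1.43 to 1.94, p = 1.1e-10 by Fisher's exact test), while at promoters the shares were 16.0% and 15.7% (odds ratio 1.02, 0.856 to 1.21). The ratio of the 2 odds ratios was 1.64 (95% Wald interval 1.31 to 2.05). Over all locations the odds ratio of X was 1.33 without the 50 kb on either side of disco-r. Against arm length X did not pass, with 18.5% of peaks beside 17.6% of sequence. The split by location was not set against length, so it holds only relative to the candidates.

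No biological explanation was tested against the technical ones, because the design has 1 group. Peaks at ribosomal protein genes were weighed first. Promoters in general do not account for them: among genes with a promoter candidate, ribosomal protein genes had a promoter peak more often than others (odds ratio 8.97, 5.44 to 15.3). Non-specific precipitation of highly transcribed chromatin stays open, because tRNA genes, which another polymerase transcribes, had a summit nearby 2.44 times as often as random windows (1.21 to 4.03, over clusters; 13 genes with 11 distinct summits). That ratio sets tRNA genes against random positions and not against other candidates, and neither a control precipitation nor expression data was used here.

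Dense peaks around disco-r were the second pattern. They do not come from 1 replicate, since the lower of the replicates' percentiles among windows was 98.8. Extra copies of the locus, brought in by the tagged transgene, may raise signal along the whole block; the pooled candidates there stood at the 94.3rd percentile, neither above the 99th, which the test set for extra copies, nor below the median, which would have argued against them. Of these 54 candidates 7.41% lay in coding exons against 12.0% elsewhere (odds ratio 0.588, 0.154 to 1.6, p = 0.402 by Fisher's exact test). Extra copies and binding of disco-r, at its own gene or at neighbours such as CG42353 and Tob, therefore cannot be told apart with these numbers.

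The third pattern was the word ACAGTG. GC content together with promoter class does not account for it, since with candidates matched on both the odds ratio was 1.98 (1.74 to 2.25). Nor does the composition of the region, since copies within 100 bp of the summit were 2.55 times as dense as those 400 to 600 bp away (2.26 to 2.92). A ratio of 1 was too low a bar, as the word also rises towards summits of candidates matched on GC content and promoter (1.56 times, 1.42 to 1.72). That rise is not enough, since the ratio in peaks was 1.64 times theirs (1.4 to 1.92). Neither matched comparison took account of position relative to the TSS. Promoter summits lay at a median of -92 bp in peaks and -10 bp in other promoter candidates, so a word placed by the TSS is not excluded. A candidate explanation is that the tagged protein, or a protein bound with it, recognises this word; it was found and tested on the same peaks, 20.5% of which hold it, and its dip at the summit itself was not accounted for.

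One hypothesis concerned promoters shared by genes on opposite strands. Of the 1215 promoter peaks 426 (35.1%, 32.4 to 37.8) lay at a divergent pair of TSSs, against 16.6% of promoter candidates that did not pass. Gene density alone may give such an excess. With strata by the number of nearby genes the odds ratio was 2.81 (2.43 to 3.26), and without them 2.71, which argues against gene density as the whole cause. The strata did not take summit position into account. Summits were upstream of the nearest TSS in 79.3% of promoter peaks and 52.2% of the other promoter candidates, so the excess was not separated from summit position.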
